A study of Daphnia magna with 3 samples.

How the data were processed

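RNA of Daphnia magna, a freshwater water flea, was profiled in 7 body parts: hemocytes (the circulating cells of the hemolymph), eggs, gut, antenna, head, carapace (the shell that encloses the trunk) and carcass, which the labels also call the body. The animals carried the genotype IL-M1-8, were kept at 20 °C in ADaM medium at 20 mL per adult, and were fed green algae daily at 100000 cells per mL, per the labels' protocols. RNA was extracted with a commercial kit and sequenced as ligation-prepared cDNA on an Oxford Nanopore instrument, per the labels' protocols, so each read comes from 1 cDNA molecule. Each of the 3 replicates, numbered 3, 4 and 7, is 1 pool in which 7 barcodes mark the body parts, which gives 21 libraries. The labels do not say whether the body parts of a replicate came from the same animals or whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

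The authors deposited 1 table that gives, for each library and each of 33957 model transcripts, the transcript length, the read count and the RPKM. The submitters' processing notes name SAMtools and DESeq2, and the aligner, the genome build and the annotation are not given in the sources used here. Each of the 33957 transcripts belongs to its own gene model, and the word gene is used for such a model throughout. The identifiers are names of gene models on 572 contigs and the deposited table pairs them with no gene name. Of these identifiers, 0 matched the RefSeq gene table of the ASM2063170v1.1 assembly, so no gene names, functions or chromosome positions are given. The gene lists that had been fixed for tissue functions (digestion, vision, neurons, chemosensory receptors, muscle, cuticle, hemocytes, germ line, cell cycle, yolk, hemoglobin, ion transport, detoxification, ribosome, respiratory chain, chaperones, developmental transcription factors, extracellular matrix and algal photosynthesis) work on gene names and so could not be applied. The lengths were multiples of 3 for 70.0% of the transcripts.

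The deposited counts are whole reads per transcript, and they were used unchanged for all tests. In the deposited RPKM values, 1 read of a given transcript was worth the same in all 7 body parts of a replicate: the implied total was 926451 reads in replicate 3, 988239 in replicate 4 and 2424632 in replicate 7, which are the sums over the 7 libraries of each replicate. RPKM therefore scaled with the number of reads of a library, which ran from 0.42% of its replicate for the gut of replicate 4 to 45.58% for the antenna of replicate 7, and was not used to compare body parts.

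Genes were tested with edgeR 4.0.16 in R 4.3.3. The filterByExpr function with its minimum count of 10 kept 4035 genes, which held between 87.5% and 96.8% of the reads of each library, and left out 29922. TMM factors scaled the libraries and ran from 0.24 in the head of replicate 4 to 2.04 in the gut of replicate 4. A quasi-likelihood model with 1 mean per body part was fitted to all 21 libraries, so that all body parts shared 1 estimate of the spread. The common dispersion was 0.29 and the prior degrees of freedom were 9.9. Genes were tested jointly for any difference among the 7 body parts, then for each body part against the unweighted mean of the other 6. A gene was called specific to a body part when it passed the test and was higher against each of the other 6 separately. The head was also set against the antenna, and the carapace against the carcass. All tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Levels are counts scaled to CPM with the TMM factors, log2 CPM values used a prior count of 2, and errors of log2 fold changes are standard errors. Where a body part had 0 reads of a gene, the fold is a lower bound against 3 reads over the group, which covers counting error only.

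Before the data were examined, the tests, the gene lists, the alternatives and a rule for the genes to be named were fixed. That rule took the largest changes among called genes that moved the same way in 3 of 3 replicates and required a gene description. With no descriptions to apply, at most 2 identifiers higher and 2 lower are given in each comparison, by the same order.

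The replicate number marks a shared barcoded pool, so libraries with the same number are paired by pool. The main fit left the number out of the model and so did not use this pairing. A model with the number as a block was an alternative. Of the 63 pairs of libraries with the same number, 28 had deviations from their body part means that correlated above 0.1 across genes. The median correlation was 0.076 (-0.46 to 0.49), against -0.046 over the 126 pairs of different body parts and numbers. Deviations from a body part mean cancel out within the body part, so these medians are tied and the second is not an independent baseline. No 2 libraries of a body part agreed within sampling noise: the chi-square per gene between them ran from 3.6 to 73.

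The test was run on simulated counts with gene means and library sizes taken from the real data, in which 200 of 4035 genes were changed. Rises and falls of several sizes were simulated, so each recovery rate covers only part of the 200 genes. Whether these rates hold for real libraries that stand apart from their body part, such as some head and gut libraries, was not tested. Of 4-fold rises it recovered 79.4% in hemocytes, 82.4% in eggs, 44.1% in gut, 67.6% in antenna, 79.4% in head, 88.2% in carapace and 91.2% in carcass. Of 4-fold falls it recovered 15.2% in hemocytes, 33.3% in eggs, 9.1% in gut, 27.3% in antenna, 12.1% in head, 12.1% in carapace and 48.5% in carcass, so falls were far harder to detect than rises. Of its calls, 10 of 117 in eggs, 8 of 118 in carcass, 6 of 94 in antenna, 3 of 94 in carapace, 2 of 85 in hemocytes, 2 of 86 in head and 0 of 52 in gut were genes that had not been changed. In eggs, carcass and antenna this was above the nominal 5%. Only a single simulation was run for each body part, which cannot tell whether the rate itself was raised.

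The alternatives were DESeq2 1.42.0 (Wald tests, and a likelihood ratio test for the joint comparison), RLE factors in edgeR, no count filter, a filter of 10 reads in 3 libraries (4988 genes), the block, voom with sample quality weights in limma 3.58.1, thinning of all libraries to 4161 reads, a fold change of at least 2, each replicate left out, and only the 6 libraries of a pair. Added after the data had been seen were each library left out in turn, the gut of replicate 4 left out with the head of replicate 3, the same with the gut of replicate 7 also left out, thinning to 26378 reads without the gut of replicate 4, and models with nearly the same counts counted once. Tables were prepared with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1.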

Results

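The series was compiled as a transcriptional atlas, and its design asks which genes each body part of Daphnia magna uses more or less than the rest of the animal. The 21 libraries held 4339322 reads on model transcripts. Eggs had 159154 to 326037 reads, carcass 177033 to 416875, head 123235 to 249289, carapace 106131 to 237842, hemocytes 59943 to 270725 and antenna 58544 to 1105094. The gut was the shallowest body part, with 32202 reads in replicate 3, 4161 in replicate 4 and 26378 in replicate 7. The largest library was 265.6 times the smallest. At least 1 read was counted for 19682 of the 33957 genes, and 398 had a read in all 21 libraries.

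Body parts differed in how evenly their reads were spread over genes. In eggs the 10 most counted genes took 8.3% ± 2.0 of the reads (SD, n = 3), and in head 48.2% ± 27.4 (SD, n = 3), with 18.9% in replicate 3, 73.1% in replicate 4 and 52.7% in replicate 7. The gut library of replicate 4 had 67.2% of its reads on 1 gene, genemark-falcon_000292F-processed-gene-0.4-mRNA-1. This gene was also the most counted in the other egg, gut and carapace libraries, from 0.94% in eggs of replicate 4 to 20.43% in the gut of replicate 3. It led in some libraries of each other body part too: hemocytes of replicates 3 and 4, the antenna of replicate 4 (22.27%), the head of replicate 3 and the carcass of replicates 3 and 7. At a common depth of 26378 reads, eggs showed 5287.3 ± 91.8 genes (SD, n = 3), gut 5157.0 ± 8.5 (SD, n = 2), carcass 4880.0 ± 296.4 (SD, n = 3), hemocytes 4691.0 ± 606.2 (SD, n = 3), carapace 4421.0 ± 703.2 (SD, n = 3), antenna 4067.3 ± 230.2 (SD, n = 3) and head 3700.3 ± 1584.6 (SD, n = 3).

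The egg libraries were the most alike and the most distinct from the other body parts. Their mean Spearman correlation across the 4035 tested genes was 0.88 among themselves and 0.14 with antenna, 0.21 with carapace, 0.28 with head, 0.34 with gut, 0.39 with hemocytes and 0.44 with carcass. The means for head, hemocytes and gut cover unlike libraries. Egg libraries correlated at 0.54 to 0.6 with the head of replicate 3 and at 0.01 to 0.23 with the other heads. The values were 0.56 to 0.6 with hemocytes of replicate 4 and 0.17 to 0.4 with the other hemocytes. They were 0.58 to 0.69 with the gut of replicate 7 and 0.14 to 0.24 with the other guts. Carapace (0.76), antenna (0.73) and carcass (0.73) libraries were also closest to a library of their own body part. Antenna and carapace correlated at 0.65, and hemocytes and carcass at 0.63. The hemocyte libraries correlated at 0.57 among themselves (lowest pair 0.41), and each was closest to a library of another body part: those of replicates 3 and 4 to the head of replicate 3 (0.69 and 0.73), and that of replicate 7 to the carapace of replicate 3 (0.73). The 3 gut libraries correlated at 0.27 among themselves. That of replicate 3 was closest to carcass of the same replicate (0.64), that of replicate 7 to eggs of the same replicate (0.69), and that of replicate 4 to hemocytes of replicate 4 (0.31). The head library of replicate 3 was closest to hemocytes of replicate 4 (0.73), whereas the heads of replicates 4 and 7 were closest to each other (0.73). Genes are not independent replicates, so these correlations describe the libraries and carry no test.

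**Figure D1:**
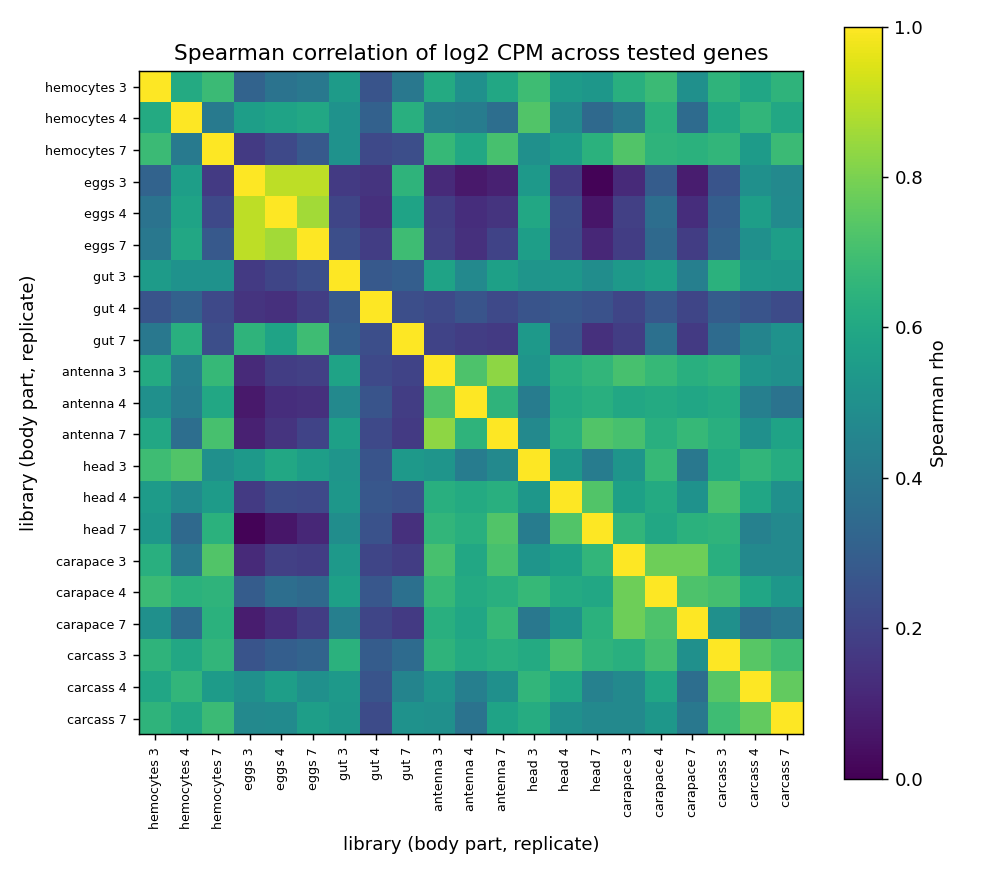
Spearman correlation of log2 CPM across 4035 tested genes for each pair of the 21 libraries, labelled on both axes by body part and replicate, with colour from 0 to 1. Eggs form a block with a mean of 0.88 within it, while the 3 gut libraries average 0.27.

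Body parts differed in 1480 genes, 36.7% of the 4035 tested (edgeR, joint test). By mean CPM, 420 of these genes were highest in carapace, 374 in eggs, 337 in antenna, 124 in head, 106 in carcass, 89 in hemocytes and 30 in gut. In the deposited RPKM, which scales with library depth, 340 of the 1480 genes (23.0%) had another body part as the highest, and the gut was the highest for 0 genes and the carcass for 241. DESeq2 called 2221 genes in the joint test. In the comparisons of 1 body part with the rest, the CPM after "against" is the mean over the other 18 libraries. The log2 fold change instead takes the unweighted mean of the fitted log levels of the other 6 body parts, so it can be far from the ratio of the 2 CPM values.

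Eggs stood apart from the other 6 body parts in both directions. In eggs 841 genes were higher and 955 lower, with median log2 fold changes of 1.65 and -3.14. The higher genes took 30.8% ± 2.1 of egg reads (SD, n = 3) and 5.5% ± 4.02 of the reads of the other libraries (SD, n = 18), where the highest share was 15.0% in the gut of replicate 7. Of the 841, 837 were higher in 3 of 3 replicates. The largest rise among the 837 was in genemark-falcon_000241F-processed-gene-0.2-mRNA-1, at 685 ± 434 CPM (SD, n = 3) against 20.8 elsewhere (log2 fold change 5.13 ± 0.52, adjusted p = 1.37e-06). Next came maker-falcon_000044F-snap-gene-6.157-mRNA-1, at 587 ± 391 CPM (SD, n = 3) against 18.7 (5.01 ± 0.51, adjusted p = 1.37e-06). No read in eggs came from maker-falcon_000000F-snap-gene-54.58-mRNA-2 (4886 reads elsewhere, at least 242-fold lower, adjusted p = 0.00287) or from maker-falcon_000001F-augustus-gene-42.61-mRNA-1 (1180 reads elsewhere, at least 118-fold lower, adjusted p = 0.000136). Against each other body part separately, 33 genes were higher in eggs. The balance of directions depended on scaling: 46.8% of the egg calls were higher with TMM factors, 68.2% with RLE factors (1534 higher, 714 lower) and 63.2% with DESeq2 (1490 higher, 867 lower). Without the egg library of replicate 3 there were 542 higher genes, and without the gut of replicate 3 there were 524 lower genes. The 33 specific genes became 12, 6 and 17 without the egg library of replicate 3, 4 and 7. They became 12 without the carcass of replicate 3 and 0 without the gut of replicate 3.

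Antennae, which in Daphnia include the swimming limbs, were higher in 472 genes and lower in 151, with median log2 fold changes of 2.47 and -3.0. The higher genes took 45.5% ± 5.57 of antenna reads (SD, n = 3) and 13.9% ± 10.2 elsewhere (SD, n = 18), with up to 36.7% in hemocytes of replicate 7. Of the 472, 408 were higher in 3 of 3 replicates. The largest rise among the 408 was in maker-falcon_000018F-snap-gene-23.93-mRNA-3, at 1260 ± 36.2 CPM (SD, n = 3) against 9.58 (log2 fold change 7.65 ± 0.51, adjusted p = 2.38e-09). Next came maker-falcon_000004F-augustus-gene-23.99-mRNA-1, at 984 ± 880 CPM (SD, n = 3) against 8.44 (7.48 ± 0.64, adjusted p = 7.82e-08). Antennae had 0 reads of maker-falcon_000000F-augustus-gene-25.32-mRNA-1 (at least 10.4-fold lower, adjusted p = 0.00814) and of maker-falcon_000005F-snap-gene-14.107-mRNA-1 (at least 9.45-fold lower, adjusted p = 0.00501), each a call lost in 6 of 33 alternatives. Antennae had 5 specific genes, a count that ran from 0 without the gut of replicate 7 to 9 without hemocytes of replicate 7. Without the antenna of replicate 7 the counts were 271 higher and 12 lower. The lower count was 25 without the antenna of replicate 3, 46 without that of replicate 4, 99 without the head of replicate 3, 56 without the carapace of replicate 4 and 54 without the gut of replicate 7.

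The carapace was higher in 480 genes and lower in 11, with median log2 fold changes of 2.24 and -1.91. The higher genes took 39.2% ± 7.84 of carapace reads (SD, n = 3) and 12% ± 8.83 elsewhere (SD, n = 18), with up to 28.5% in hemocytes of replicate 7. Of the 480, 479 were higher in 3 of 3 replicates. The largest rise among the 479 was in snap_masked-falcon_000016F-processed-gene-17.87-mRNA-1, at 268 ± 165 CPM (SD, n = 3) against 9.47 (log2 fold change 5.75 ± 0.71, adjusted p = 2.43e-05). Next came maker-falcon_000018F-augustus-gene-10.50-mRNA-1, at 181 ± 98.1 CPM (SD, n = 3) against 9.02 (5.24 ± 0.64, adjusted p = 1.39e-05). The carapace had 0 reads of augustus_masked-falcon_000071F-processed-gene-1.68-mRNA-1 (at least 2.62-fold lower, adjusted p = 0.0186) and 29.3 ± 36.6 CPM (SD, n = 3) of maker-falcon_000042F-augustus-gene-2.61-mRNA-1 against 181 (log2 fold change -2.46 ± 0.77, adjusted p = 0.0358), calls lost in 9 and 5 of 33 alternatives. No gene was specific to the carapace by edgeR (57 at an unadjusted p under 0.05, 3 by DESeq2, 6 by limma voom). The higher count was 286 without the carapace of replicate 3 and 302 without that of replicate 7. The lower count was 1 without either of these and 21 without the carapace of replicate 4. It ran from 5 to 18 without eggs of replicate 3 (7), eggs of replicate 7 (7), gut of replicate 4 (18), gut of replicate 7 (5) or head of replicate 7 (17).

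The head was higher in 93 genes, and these had the steepest rises among the 7 body parts, with a median log2 fold change of 5.36. They took 44.5% ± 34.8 of head reads (SD, n = 3) and 1.44% ± 3.16 elsewhere (SD, n = 18), where the highest share was 14.0% in the carcass of replicate 3. Their median log2 difference from the other 6 body parts of the same replicate was 4.88 in replicate 4 and 4.90 in replicate 7 but 0.21 in replicate 3, and 51 of the 93 were higher in 3 of 3 replicates. The largest rise among the 51 was in maker-falcon_000031F-augustus-gene-9.85-mRNA-1, at 2660 ± 3460 CPM (SD, n = 3) against 8.54 (log2 fold change 10.35 ± 1.18, adjusted p = 1.54e-05). Next came maker-falcon_000023F-augustus-gene-16.69-mRNA-1, at 7420 ± 10900 CPM (SD, n = 3) against 42.4 (10.31 ± 1.03, adjusted p = 6.62e-07). The DESeq2 test did not call the first of these 2. By edgeR, 0 genes were lower in head (38 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma voom), and 4 were specific to it. Without the head library of replicate 3, the counts were 178 higher, 13 lower and 31 specific. The specific count was 28 without the carcass of replicate 3, 0 without a gut library, without the head of replicate 7 or without the carcass of replicate 4, 1 without an egg library, and 2 without hemocytes of replicate 3 or 7 or the antenna of replicate 7.

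The carcass was higher in 100 genes, 97 of them in 3 of 3 replicates, with a median log2 fold change of 3.01. They took 12.5% ± 9.42 of carcass reads (SD, n = 3) and 1.52% ± 1.46 elsewhere (SD, n = 18), with up to 5.07% in the gut of replicate 3. The largest rise among the 97 was in snap_masked-falcon_000004F-processed-gene-7.92-mRNA-1, at 399 ± 352 CPM (SD, n = 3) against 70.8 (log2 fold change 4.93 ± 0.77, adjusted p = 0.00066). The 70.8 CPM is a mean over 18 libraries that include hemocytes at 288 CPM, and the fold change averages log levels by body part, so the 2 do not give the same ratio. Next came augustus_masked-falcon_000004F-processed-gene-7.59-mRNA-1, at 390 ± 353 CPM (SD, n = 3) against 69.0 (4.91 ± 0.83, adjusted p = 0.00102). These models lie on the same contig with 458 and 450 reads in carcass, correlated at 0.99 across the 21 libraries, and are reported as uncertain, since they can hold the same reads. The 1 lower gene was maker-falcon_000016F-augustus-gene-6.57-mRNA-2, at 16.5 ± 4.13 CPM (SD, n = 3) against 147 (log2 fold change -2.41 ± 0.65, adjusted p = 0.0452), a call lost in 17 of 33 alternatives. DESeq2 called 69 higher and 19 lower, so that 78.4% of its calls were higher against 99.0% by edgeR. No gene was specific to the carcass (11 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma voom). Without the carcass library of replicate 3 there were 64 higher genes. Without hemocytes of replicate 3, eggs of replicate 4, the gut of replicate 3 or 4, the antenna of replicate 3, the head of replicate 7 or the carcass of replicate 4 or 7 there was no lower gene, and without the gut of replicate 7 there were 5.

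Hemocytes were higher in 99 genes, with a median log2 fold change of 2.95, and 46 of these were higher in 3 of 3 replicates. The higher genes took 6.24% ± 6.18 of hemocyte reads (SD, n = 3) and 1.91% ± 1.75 elsewhere (SD, n = 18), with up to 5.62% in the carapace of replicate 3. Their median log2 difference from the other body parts was 3.61 in replicate 7, 1.34 in replicate 3 and 0.09 in replicate 4. The largest rise among the 46 was in snap_masked-falcon_000004F-processed-gene-7.92-mRNA-1, at 288 ± 377 CPM (SD, n = 3) against 89.2 (log2 fold change 4.42 ± 0.81, adjusted p = 0.00467), which was also among the carcass genes. The 89.2 CPM is a mean over 18 libraries that include carcass at 399 CPM, so it lies closer to the hemocyte level than the fold change does. Next came augustus_masked-falcon_000016F-processed-gene-20.81-mRNA-1, at 1740 ± 2440 CPM (SD, n = 3) against 160 (4.18 ± 0.63, adjusted p = 0.00063). Without hemocytes of replicate 7 neither gene was called. With single replicates or libraries left out these log2 fold changes ran from 2.14 to 5.65 and from 1.57 to 5.76, and the calls were lost in 4 and 3 of 34 alternatives. By edgeR, 0 genes were lower (20 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma voom) and 0 were specific (3 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma voom). With the replicate as a block 55 genes were higher, DESeq2 called 24 and limma voom 3. The count was 0 without hemocytes of replicate 7, 223 without hemocytes of replicate 4 and 178 without the gut of replicate 3.

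The gut was higher in 10 genes, which took 0.442% ± 0.717 of gut reads (SD, n = 3) and 0.0639% ± 0.0754 elsewhere (SD, n = 18). Of the 10, 8 were higher in 1 of 3 replicates: their set had a median log2 difference of 4.64 in replicate 3, -0.83 in replicate 4 and -1.34 in replicate 7. The 1 gene higher in 3 of 3 replicates was maker-falcon_000000F-augustus-gene-26.6-mRNA-4, at 358 ± 475 CPM (SD, n = 3) against 74.0 (log2 fold change 2.53 ± 0.54, adjusted p = 0.0396), a call lost in 13 of 33 alternatives, the replicate as a block among them. By edgeR, 0 genes were lower in gut (369 at an unadjusted p under 0.05, 6 by DESeq2, 0 by limma voom, and 2 by edgeR without hemocytes of replicate 4 or 7 or the antenna of replicate 4) and 0 were specific (0 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma voom). With the replicate as a block the higher count was 0, and by limma voom 0. It was 0 without the gut of replicate 3, 28 without the gut of replicate 7 and 17 without the antenna of replicate 7.

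**Figure D2:**
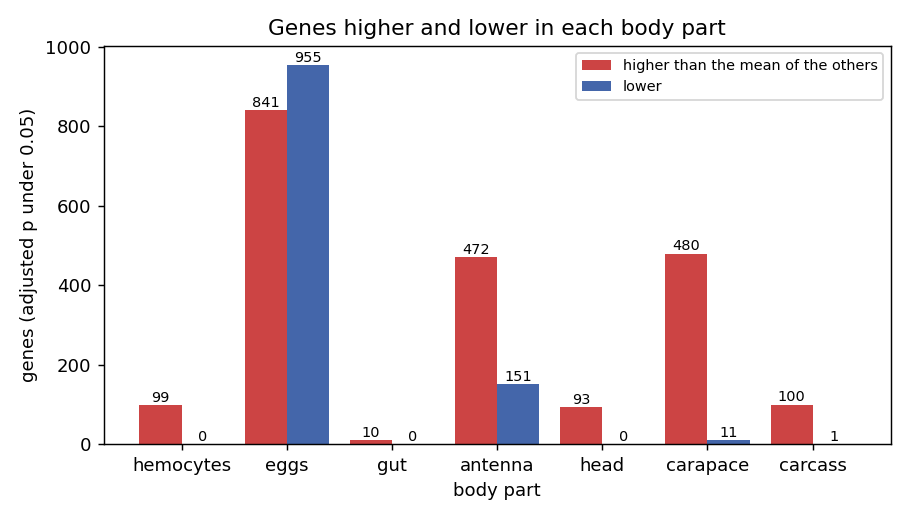
Number of genes with an adjusted p under 0.05 (edgeR), by body part on the horizontal axis, higher (red) or lower (blue) than the mean of the other 6 body parts. Eggs had 841 and 955, while gut had 10 and 0.

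**Figure D3:**
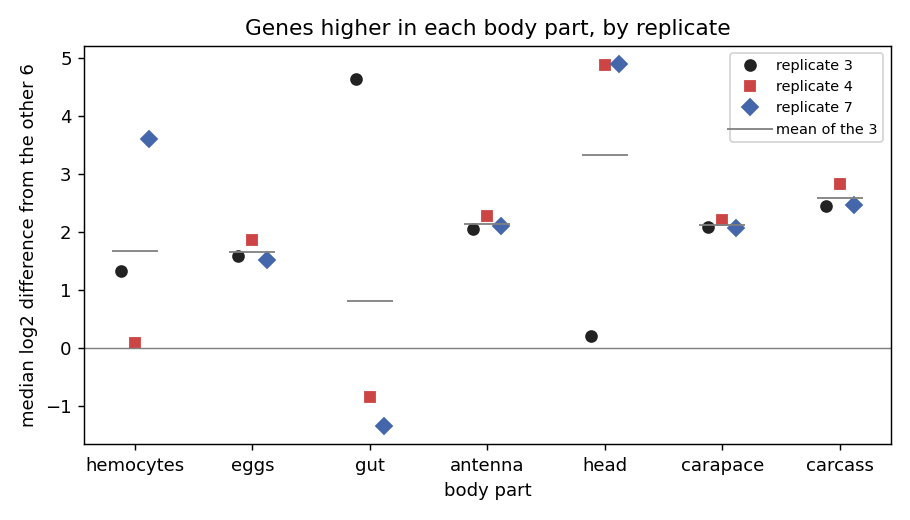
Median log2 difference between a body part and the other 6 of the same replicate over the genes called higher in that body part; points are the 3 replicates and grey lines their mean. The head set stood at 4.88 and 4.90 in replicates 4 and 7 and at 0.21 in replicate 3, and the gut set was above 0 only in replicate 3 (4.64).

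Head and antenna, body parts that both carry nervous and sensory tissue, differed in 49 genes: 32 were higher in head and 17 in antenna. The median log2 fold changes were 6.23 and -4.62. The genes named here are those with the largest differences among called genes that pointed the same way in 3 of 3 replicates. The largest difference toward the head was in maker-falcon_000022F-augustus-gene-13.124-mRNA-3, at 18400 ± 20200 CPM (SD, n = 3) against 20.3 ± 18.7 (log2 fold change 9.61 ± 2.36, adjusted p = 0.0458). Next came augustus_masked-falcon_000023F-processed-gene-12.7-mRNA-1, at 15200 ± 19100 CPM (SD, n = 3) against 22.3 ± 12.2 (9.25 ± 2.10, adjusted p = 0.03). Toward the antenna it was in maker-falcon_000005F-snap-gene-29.97-mRNA-5, with 1 read in head and 283 in antenna (log2 fold change -7.93 ± 1.20, adjusted p = 0.000624), followed by maker-falcon_000004F-augustus-gene-23.99-mRNA-1, with 1 read in head and 282 in antenna (-7.76 ± 1.32, adjusted p = 0.00267). The call of maker-falcon_000022F-augustus-gene-13.124-mRNA-3 was lost in 14 of 34 alternatives, the replicate as a block among them, and that of augustus_masked-falcon_000023F-processed-gene-12.7-mRNA-1 in 7 of 34. Without replicate 4 as a whole, edgeR called 0 higher and 0 lower, without replicate 3 it called 51 and 15, and without replicate 7 38 and 39. Without the head of replicate 3 the counts were 54 higher and 9 lower, and without the head of replicate 4 they were 14 and 6. Without the antenna of replicate 3 they were 14 and 5, and without that of replicate 7 they were 8 and 8. They were 16 and 6 without the gut of replicate 4, and 13 were higher without the antenna of replicate 4. The lower count was 30 and 35 without hemocytes of replicate 4 and 7, 35 and 29 without the gut of replicate 3 and 7, and 11 without eggs of replicate 7.

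Carapace and carcass, body parts that both carry epidermis and cuticle, differed in 280 genes: 226 were higher in carapace and 54 in carcass, and all of these pointed the same way in 3 of 3 replicates. The median log2 fold changes were 3.01 and -3.57. The largest difference toward the carapace was in maker-falcon_000018F-augustus-gene-21.133-mRNA-1, at 350 ± 183 CPM (SD, n = 3) against 4.78 ± 1.09 (log2 fold change 6.02 ± 0.94, adjusted p = 0.00306). Next came snap_masked-falcon_000016F-processed-gene-17.87-mRNA-1, at 268 ± 165 CPM (SD, n = 3) against 6.75 ± 11.7 (5.27 ± 1.03, adjusted p = 0.00629). Toward the carcass it was in genemark-falcon_000021F-processed-gene-6.28-mRNA-1, with 1 read in carapace and 310 ± 177 CPM in carcass (SD, n = 3; log2 fold change -6.58 ± 1.07, adjusted p = 0.00306), followed by maker-falcon_000001F-augustus-gene-8.28-mRNA-1, with 0 reads in carapace and 42 in carcass (at least 5.64-fold lower, adjusted p = 0.0485), a call lost in 18 of 33 alternatives, the replicate as a block among them. Without replicate 4 as a whole, edgeR called 0 higher and 0 lower, without replicate 3 it called 82 and 21, and without replicate 7 108 and 34. Without the carcass of replicate 4 the counts were 5 higher and 2 lower, without the carcass of replicate 7 they were 48 and 19. Without the carapace of replicate 3 they were 113 and 14, and without that of replicate 7 they were 87 and 5. The lower count was 31 without the carapace of replicate 4 and 84 without the head of replicate 3.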

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

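The settings that left out single libraries, thinned to 26378 reads, left out libraries in doubt or merged models with nearly the same counts were chosen after the data had been seen; the others were planned. Of the 26 counts of genes, 0 moved by over 1.5 times with a fold change of at least 2, 1 with the filter of 10 reads in 3 libraries, 3 with the block, 5 with RLE factors, 12 with DESeq2, 13 with limma voom, 17 with no count filter and 19 with either thinning. Without replicate 3, 4 and 7 it was 14, 16 and 9 of the 26. Thinning removes reads by construction, and for the other moves the cause was not tested. RLE factors moved the median log2 fold change of all tested genes by 0.56 in eggs, 0.20 in gut, -0.17 in hemocytes, -0.22 in head, -0.15 in carapace and -0.14 in carcass against TMM. The planned tests of gene lists were not run, since no gene names were matched.

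With RLE factors, 55 genes were higher in hemocytes, 1534 higher and 118 specific in eggs, 0 specific to head and 2 lower in carcass. With DESeq2, 2221 differed among body parts, 24 were higher in hemocytes, 1490 higher and 133 specific in eggs, and 6 higher and 6 lower in gut. It gave 14 specific to antenna, 41 lower and 3 specific in carapace, 19 lower in carcass, 69 lower in head than antenna and 86 lower in carapace than carcass. With no count filter, 2869 differed among body parts, 288 were higher and 1 specific in hemocytes, 1451 higher in eggs, and 55 higher and 10 lower in gut. That setting gave 1289 higher and 21 specific in antenna, 398 higher and 68 specific in head, 4 specific to carapace and 381 higher, 9 lower and 2 specific in carcass. Of the pairs, 124 were higher and 187 lower in head than antenna, and 192 lower in carapace than carcass. The filter of 10 reads in 3 libraries kept 4988 genes, more than the 4035 of filterByExpr, and moved 1 count, to 2 lower genes in carcass. With the replicate block, 55 were higher in hemocytes, 0 in gut and 2 lower in carcass, and no other count moved by over 1.5 times; 3 named calls were lost with it. With limma voom and sample weights, 3 were higher in hemocytes, 85 specific to eggs and 0 higher in gut. It gave 291 lower and 11 specific in antenna, 1 specific to head, 65 lower and 6 specific in carapace, and 16 lower in carcass. Of the pairs, 57 were higher and 32 lower in head than antenna, and 397 higher and 137 lower in carapace than carcass. Only the 6 libraries of the pair gave 11 higher in head than antenna and 241 lower in carapace than carcass.

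Thinned to 4161 reads, 99 genes passed the filter against 4035 at full depth, and 55 of them differed among body parts, 2 were higher in hemocytes, 14 higher, 15 lower and 4 specific in eggs and 1 higher in gut. There were 26 higher, 1 lower and 0 specific in antenna, 9 higher and 0 specific in head, 10 higher and 2 lower in carapace, and 7 higher and 0 lower in carcass. Of the pairs, 8 were higher and 0 lower in head than antenna, and 10 higher and 5 lower in carapace than carcass. Thinned to 26378 reads without the gut of replicate 4, 1119 genes passed the filter and 447 differed, 12 were higher in hemocytes, 230 higher, 288 lower and 4 specific in eggs and 5 higher in gut. There were 182 higher, 38 lower and 1 specific in antenna, 48 higher and 0 specific in head, 130 higher and 4 lower in carapace, and 29 higher and 0 lower in carcass. Of the pairs, 3 were higher and 3 lower in head than antenna, and 60 higher and 14 lower in carapace than carcass. The counts under thinning thus fell together with the number of genes tested. Without the gut of replicate 4 and the head of replicate 3, 85 were lower in antenna, 165 higher, 12 lower and 7 specific in head, 7 lower in head than antenna and 92 lower in carapace than carcass. With the gut of replicate 7 also left out, 61 were higher in hemocytes, 37 higher in gut, and 40 lower and 0 specific in antenna. There were then 157 higher, 11 lower and 0 specific in head, 9 lower in carcass, 59 higher in head than antenna and 94 lower in carapace than carcass. The lone gut library is here assumed to vary like the others. Counting models with nearly the same counts once moved 1 count, to 1 gene specific to carapace.

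Leaving out each replicate or each library in turn, the number of genes ran from 753 to 1721 for any difference among body parts, from 0 to 223 higher and 0 to 1 lower in hemocytes. It ran from 423 to 980 higher, 239 to 984 lower and 0 to 44 specific in eggs, from 0 to 56 higher and 0 to 2 lower in gut. The range was from 255 to 585 higher, 7 to 212 lower and 0 to 9 specific in antenna, and from 58 to 181 higher, 0 to 13 lower and 0 to 45 specific in head. It was 286 to 551 higher, 1 to 21 lower and 0 to 1 specific in carapace, and 34 to 147 higher and 0 to 5 lower in carcass. For the pairs it was 0 to 54 higher and 0 to 39 lower in head than antenna, and 0 to 262 higher and 0 to 84 lower in carapace than carcass. The values of 0 in both pairs were reached without replicate 4. Over all settings, the 28 named results gave the same direction and call 827 times, lost the call 112 times and reversed 1 time. Of the 28, 9 were called under all settings tried for them and 19 lost the call under at least 1. The reversal was in gut: maker-falcon_000000F-augustus-gene-26.6-mRNA-4 had a log2 fold change of -0.09 without the gut of replicate 3, against up to 3.14 without the gut of replicate 7.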

Other observations

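The tests of exchanged labels, of egg or carcass RNA in gut libraries, of the spread between libraries beside the gut tests and of models with nearly the same counts were chosen only after the result was seen.

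Genes higher in the same body part lay near each other on the contigs. With models of nearly the same counts merged, 44.2% of 95 genes higher in hemocytes shared contig and segment number, as given in the model names, with another such gene, against 10.4% in random draws of tested genes matched on expression. The share was 44.3% of 97 genes in carcass against 10.6%, and 28.4% of 88 in head against 9.5%. It was 51.8% of 461 in antenna against 41.1%, 52.1% of 472 in carapace against 41.6% and 61.4% of 823 in eggs against 57.8%. In 1000 draws the permutation p was 0.000999, the smallest they can give, for hemocytes, antenna, carapace and carcass (adjusted p = 0.0015 over 6 body parts), 0.002 for head (adjusted p = 0.0024) and 0.029 for eggs (adjusted p = 0.029). The enrichment was 4.25 times the random share in hemocytes, 4.18 in carcass, 2.99 in head, 1.26 in antenna, 1.25 in carapace and 1.06 in eggs. Larger sets have larger random shares, which limits how high their ratio can be. The ratios therefore do not rank the body parts by clustering. These shares are what neighbouring genes used in the same body part would give, as a hypothesis. Genes split into several models, or reads counted for more than 1 model, could give the same result. The merging, limited to models with at least 100 reads, covers this only in part. Among the carcass genes, snap_masked-falcon_000004F-processed-gene-7.92-mRNA-1 and augustus_masked-falcon_000004F-processed-gene-7.59-mRNA-1 can hold the same reads but stayed unmerged and counted as neighbours.

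The head library of replicate 3 lacked much of what the other 2 heads shared. Genes called higher in eggs took 10.6% of its reads, against 0.998% in the head of replicate 4 and 1.41% in that of replicate 7. The 181 genes higher in head from replicates 4 and 7 alone had a mean log2(CPM + 10) of 9.42 and 9.58 in those heads and 6.09 in the head of replicate 3, where 96.1% of them were lower. The carcass of replicate 3 held them at 7.61 against 5.98 and 6.06 in the other carcasses. These genes were chosen as high in the heads of replicates 4 and 7 over the other body parts of those replicates, carcass included. Part of both gaps therefore follows from the choice. For comparison, 95 carcass genes chosen in the same way stood at 8.31 in the carcass of replicate 3, against 8.57 and 8.52 in the other carcasses. Exchanged head and carcass labels are argued against by the 95 carcass genes of replicates 4 and 7, which were higher in the carcass of replicate 3 than in its head by a median log2 difference of 3.05 (bootstrap interval over genes 2.90 to 3.45). After 19 leading transcripts were removed, the median difference between the head of replicate 3 and the others was -2.88 (-3.22 to -2.59) over the 170 head genes left. Before the removal it was -2.93. This argues against a few dominant genes as the whole reason for a gap that partly follows from the choice of genes. The bootstrap intervals are over genes within single libraries and do not cover the spread between libraries. Head tissue in the carcass library of replicate 3 stays open, since the excess there followed the head level across the head genes with a Spearman rho of 0.40 (0.24 to 0.53), between the bounds of 0.3 and 0.5 set beforehand, and no biological explanation was tested.

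By Spearman correlation at unequal depths, the 3 gut libraries had the lowest mean within a body part (0.27). By chi-square per gene, also at unequal depths, they did not differ most: gut pairs gave 6.9 to 13.2 and head pairs 30 to 73. Low depth stays open as the reason for the low correlation. Thinned to 26378 reads, the guts of replicates 3 and 7 correlated at 0.29, and the lowest pairs of hemocytes and of head at 0.34. That margin of 0.05 is below the SD of 0.11 between the 3 hemocyte pairs, and the gut of replicate 4, at 4161 reads, was outside this test. Carcass RNA in the gut library of replicate 3 also stays open. It was examined with 113 genes called higher in carcass with the gut libraries left out of the fit. That choice makes the genes low in the other body parts but not in gut, so a gap toward the gut is partly built in. They stood in the gut of replicate 3 at a median of 56.9% of their carcass level against at most 37.4%, in the head of replicate 4, and 13.8% ± 12.5 over the 16 other libraries compared (SD between libraries). The bootstrap interval of the difference from that head, 6.31 to 36.6 percentage points, is over genes within single libraries and does not cover the spread between libraries. Egg RNA in the gut library of replicate 7 stays open, because 98 genes called specific to eggs with the gut libraries left out of the fit stood there at a median of 24.0% of their egg level and at 23.8% in the carcass of replicate 7 (bootstrap interval over genes -7.64 to 4.75). No biological explanation was tested.

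Some models had counts closer than sampling noise allows. Of 9142 pairs of models with the same contig and segment number, 81 (counting interval 64.3 to 100.7) lay in the lower 0.1% of the distribution that independent reads give, which is 8.9 times the 9.1 pairs expected at most, and 4 of the 81 had identical counts in all 21 libraries. Pairs on the same contig with another segment number gave 26 of 210956, 4 of them identical, and pairs on different contigs gave 0 of 100000. More pairs in that tail is what the same reads counted for more than 1 model would give. The bound had first been set at 10 times the expected number, which the 8.9 times did not reach. It was replaced by the counting interval once the result was seen. That interval treats pairs as independent, but the 81 pairs hold 124 models, some of them in several pairs. It therefore cannot decide against separate neighbouring genes with like expression. The 81 and 26 pairs together hold 156 of the tested models (3.87%).

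Body part labels were shuffled within each replicate, for 100 assignments with the real one included. Only 1 of 100, the real one, reached 1480 genes with any difference (highest other 676), which argues against chance for that joint count. No other assignment reached the 99 higher in hemocytes (highest other 63), 841 higher, 955 lower and 33 specific in eggs (241, 470 and 0), 472 higher in antenna (413), 93 higher in head (69) and 480 higher in carapace (436). Each assignment shuffled all 7 body parts at once and so also broke up real groups such as the eggs. These shares therefore cannot decide chance for the count of any single body part. The hemocyte count also rests largely on 1 library: it was 0 without hemocytes of replicate 7, 24 with DESeq2 and 3 with limma voom, and the median log2 difference of these genes was 3.61 in replicate 7 and 0.09 in replicate 4. Few assignments reached the 151 lower and 5 specific genes in antenna (2 of 100 each, highest other 707 and 17), 4 specific genes in head (2 of 100, highest other 13) and 11 lower genes in carapace (3 of 100, highest other 225). These shares are not adjusted for the number of counts examined, so chance is not excluded for them. With single replicates or libraries left out, these counts ran from 7 to 212, 0 to 9, 0 to 45 and 1 to 21. For 10 genes higher in gut (26 of 100, highest other 154), and for 100 higher and 1 lower in carcass (5 of 100 each, highest other 213 and 259), chance cannot be excluded either. For the counts of 0, 100 of 100 assignments reach them by construction: the highest others were 2 lower and 0 specific in hemocytes, 10 and 0 in gut, 8 lower in head, 0 specific in carapace and 30 specific in carcass. Assignments that called several times the real count point to a structure of the samples: those with 707, 225 and 259 lower genes kept 2 egg libraries under 1 label, the one with 154 genes higher in gut did too, and those with 17, 13 and 30 specific genes in antenna, head and carcass joined the heads of replicates 4 and 7 with the carcass of replicate 3. Each pair allows 10 splits of its 6 libraries, too few for a share under 0.05: the real counts of 32 and 17 for head and antenna and 226 and 54 for carapace and carcass were each reached by 1 split, the real one, and the highest others were 5 and 0. Under the 100 shuffled assignments of all body parts, the 32 higher and 17 lower genes in head than antenna were reached by 1 and 3 (highest other 27 and 22). The 226 higher and 54 lower genes in carapace than carcass were each reached by 1 (highest other 1 and 43).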
